A study of Mus musculus with 17 samples.

How the data were processed

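RNA of sorted CD4+ CD45.1+ SMARTA T cells was measured in 17 libraries, which the labels place in 6 groups. Per the labels' protocols, mice were infected with the Armstrong strain of lymphocytic choriomeningitis virus and killed on day 54. Mucosal tissues were digested with enzymes, cells were sorted by CD62L and CD69 on a FACSAria II, RNA was taken with QIAshredder and RNeasy micro columns, and libraries were made with a stranded total RNA kit for picogram input. The growth protocol names P14 CD8 cells where all other labels name SMARTA CD4 cells, and receptor segments were checked for that reason. The deposited values are raw read counts per Ensembl gene of mm10/GRCm38, made by the authors with featureCounts per the submitters' processing notes. The notes also name cutadapt, FastQC 0.11.5, Trimmomatic 0.33, HISAT2 2.0.2, Picard 1.126 and SAMtools 1.3. The annotation release, the strand setting and the handling of duplicate reads are not given in the sources used here. Reads of overlapping or antisense genes cannot be told apart without the strand setting, and Hspa1a, Ly6c2, Defa24 and Hbb-bt have near-identical copies, so that their counts are uncertain.

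The table held 47729 genes, of which 47224 matched a symbol in the GENCODE M21 annotation used here for names, lengths and positions, and 505 did not. The 17 files per library were identical to its columns. Total counts ran from 2964988 in FRT replicate 3 to 7321889 in splenic TRM replicate 1. After the low-count filter filterByExpr, 17134 genes were tested, which held at least 99.1% of each library's counts. TMM factors ran from 0.663 in FRT replicate 3 to 1.27 in TEM replicate 2. Levels are CPM scaled by them, and shares and marker sums are CPM of total counts.

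Comparisons used edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, robust, two-sided, with 1 mean per group over all libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 22.1% with 11 residual degrees of freedom. Mucosal TRM is the mean of FRT, IEL and LP TRM with equal weight, and circulating cells are the mean of TCM and TEM. The comparisons, tests, alternatives and 28 gene lists were fixed before the data were examined, except where the text says otherwise. Core genes were called the same way in all of the tissue contrasts against TEM and TCM. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The mucosal signature was tested with fry of limma, against no change, adjusted over its higher and lower set. Principal components used log2 CPM of the 500 most variable genes with a prior count of 2. Shares of counts carry exact Clopper-Pearson intervals at 95%. Splits of the libraries, at most 100 per comparison, were drawn with a fixed seed. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for checks and figures.

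The lists, written from general knowledge, cover the sorting gates, residency, circulation, homing receptors, immediate early, heat shock, TGF-beta response, aryl hydrocarbon receptor target, cytotoxic and NK receptor, cytokine and chemokine, inhibitory and costimulatory, Th1, Th2, Th17 and type 3, follicular helper, regulatory T cell, interferon-stimulated, cell cycle, glycolysis and lipid genes. The others hold markers of intestinal epithelium, FRT epithelium, stroma, endothelium, myeloid, B and plasma, erythroid and platelet, and CD8, NK and gamma-delta T cells. They have 537 entries, 4 of them not in the table. Other lists also hold 6 of 25 intestinal epithelium markers, 5 of 17 FRT epithelium markers, 5 of 16 CD8, NK and gamma-delta T cell markers, 1 of 20 myeloid markers, 14 of 33 residency genes and 11 of 25 circulation genes. The stroma, endothelium, B and plasma, and erythroid lists share no gene with another list. Named genes are at most 6 called members per list and comparison by smallest adjusted p, uncalled members where a sentence needs them, the 8 highest and lowest fold changes per comparison at 10 CPM or more without overlap between groups, and 12 core genes per direction. Predicted genes, immunoglobulin and receptor segments, ribosomal and mitochondrial genes were left out of the last parts, and receptor segments are named for label checks alone.

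After the comparisons had been run, the tests were tested on simulated data with the means, dispersions and library sizes of these samples and 200 genes changed. For splenic TRM against TEM, edgeR recovered 40% of genes changed 2-fold and 69% of those changed 4-fold, out of 17134 genes in the fit. That missed a recovery bar of 80% set before the simulation. After that was seen, the bar was applied to 4-fold changes at 10 CPM or more, where 98.2% were recovered against 30.2% below that level. For IEL against LP TRM the shares were 29% and 64%, and 93% at the higher level. Of the genes called, 2.68% in the first simulation and 3.12% in the second were unchanged ones, and DESeq2 1.42.0 gave 12.8% and 9.26%.

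The replicate numbers of the labels did not pair the samples. The residuals of libraries with the same number in different groups had a mean r across genes of -0.001 over 26 pairs, and 1 of 14 libraries was closest to its own number. Between libraries of a group, the median ratio to counting noise was 1.42 to 4.08 without FRT replicate 3 and the library labelled TCM replicate 3, with a coefficient of variation of 3.15% for abundant genes between TCM replicates 5 and 6, against 48.8% between FRT replicates 1 and 3. An alternative chosen after the data were seen therefore summed the close libraries (FRT 1 and 2, TCM 5 and 6, and all libraries of each other group), which leaves the spread to FRT and TCM alone. Other alternatives were RLE scaling, DESeq2, no filter, limma-voom with quality weights, a replicate block, the compared groups fitted alone and each library left out. Further ones chosen after the data were seen left out FRT replicate 3 and the library labelled TCM replicate 3, subtracted a background in proportion to gene length, or kept protein-coding genes.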

Results

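The series measured RNA in memory CD4+ T cells of mice by total RNA sequencing. The cells were CD45.1+ SMARTA T cells, which carry a transgenic receptor for a peptide of lymphocytic choriomeningitis virus, sorted 54 days after infection with the Armstrong strain. The 17 libraries form 6 groups. Tissue-resident memory cells (TRM), sorted as CD62L- CD69+, came from the female reproductive tract (FRT, 3 libraries), the epithelium of the small intestine (IEL, 2), its lamina propria (LP, 3) and the spleen (3). Circulating cells came from the spleen as central memory cells (TCM, CD62L+ CD69-, 3) and effector memory cells (TEM, CD62L- CD69-, 3). Total counts were 5153943, 5020623 and 2964988 in FRT replicates 1, 2 and 3, 6003809 and 5765069 in IEL replicates 1 and 2, and 5578837, 7317095 and 4991374 in the LP libraries. They were 7321889, 5581644 and 5314369 in splenic TRM, 4590664, 4280317 and 4503986 in TEM, and 3764902, 3732596 and 3625673 in TCM replicates 3, 5 and 6. A gene with no count in a library was below 0.410 to 1.01 CPM (counts scaled to the library total), the level of 3 counts per library. Levels of single genes are means of TMM-scaled CPM ± SD (n = 3 libraries, 2 for IEL), and values given for genes without a unit are log2 fold changes ± SE. Rose, fell and called are used of genes that passed the test, and the rest of a list did not pass. FRT replicate 3 stood apart from FRT replicates 1 and 2, which widens the SD of FRT TRM. Nothing in the sources used here says that the libraries of a group came from separate animals, so that every p measures the spread between these samples, which may be technical. Intervals and floors cover counting error only, since the reads carried no molecular identifiers.

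The sorted cells carried the receptor that the cell type labels name. Trbv13-1, the beta chain segment of the SMARTA receptor, took 98.3% of all Trbv counts in the lowest library (exact Clopper-Pearson 95% interval 97.8 to 98.7) and up to 99.9% in the others, and the Trav14 family took 81.5 to 92.9% of Trav counts. The growth protocol names P14 CD8 T cells, and Trbv13-3, the segment of the P14 receptor, had at most 3 counts per library. Cd69, which marks recent activation and residency (ENSMUSG00000030156, chromosome 6, 129267325 to 129275436 of GRCm38), stood at 657 ± 52.3 and 759.8 ± 24.5 CPM in IEL and LP TRM, 309 ± 87.1 in FRT TRM and 238 ± 19.8 in splenic TRM, against 177 ± 9.94 in TEM and 74.2 ± 24.1 in TCM. Cd4 was counted in every group, from 730.3 ± 324 CPM in FRT TRM, with 356 in replicate 3, to 1299 ± 7.28 in IEL TRM. Cd8a was highest in IEL TRM, at 19.3 ± 4.58 CPM, and stood at 3.35 ± 1.56 in LP TRM.

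Libraries fell together by tissue. The first principal component held 62.9% of the variance of the 500 genes of highest variance and the next held 26.1%. Across genes, log2 CPM of IEL and LP TRM correlated with a mean Pearson r of 0.923, FRT TRM with LP TRM at 0.817 and FRT TRM with IEL TRM at 0.766. Within the spleen, TRM stood closer to TCM (mean r 0.959) than to TEM (0.929), and TEM to TCM at 0.927. TEM libraries counted 39.2 to 45.4% of olfactory receptor genes, against 1.47 to 1.83% in splenic TRM and 1.10 to 1.56% in TCM, and r was not computed without such counts. LP TRM and splenic TRM correlated at 0.886. Within groups the mean r was 0.905 in FRT TRM, where replicate 3 stood apart, and 0.961 to 0.981 in the other groups. Genes are not independent replicates, and no test was made of these values.

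**Figure D1:**
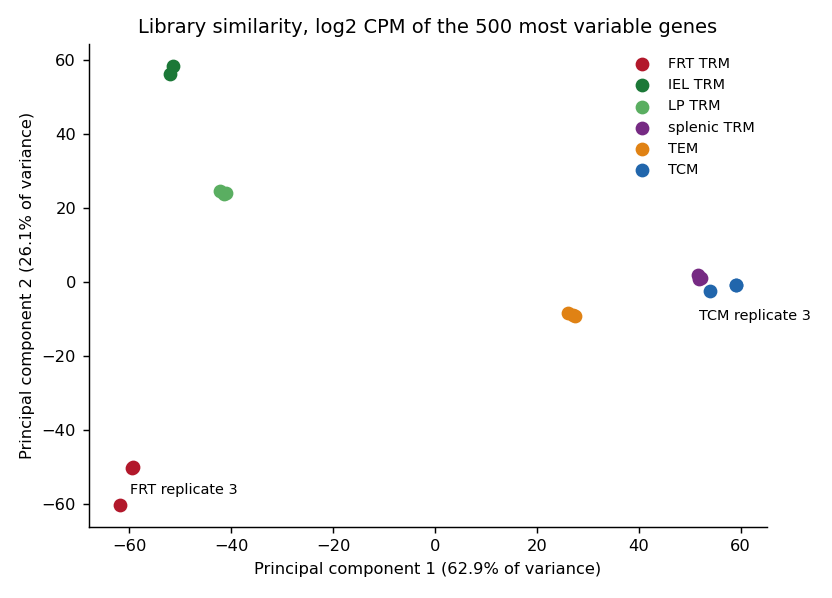
Each point is 1 library, placed by principal components 1 and 2 of log2 CPM (arbitrary units), with 62.9% and 26.1% of the variance, and coloured by group. Splenic libraries lie between 26.1 and 59.2 on component 1, and FRT replicate 3 lies apart from FRT replicates 1 and 2 at -60.2 on component 2.

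The first comparison asked what sets resident cells of the 3 mucosal sites, averaged with equal weight, apart from circulating TCM and TEM. Mucosal TRM held more mRNA of residency genes and less of genes for recirculation. Cxcr6, a chemokine receptor of tissue T cells (ENSMUSG00000048521, chromosome 9, 123806475 to 123811760), stood at 395 ± 90.7, 496 ± 18.5 and 429.7 ± 42.6 CPM in FRT, IEL and LP TRM against 40.6 ± 3.56 in TEM and 67.4 ± 19.6 in TCM, a log2 fold change of 3.07 ± 0.14 (edgeR adjusted p = 8.76e-16). Rgs1, which dampens G protein signals of chemokine receptors (ENSMUSG00000026358, chromosome 1, 144242296 to 144249242), rose by 5.03 ± 0.16 (edgeR adjusted p = 9.86e-19). S1pr1, the receptor through which T cells leave tissue toward blood and lymph (ENSMUSG00000045092, chromosome 3, 115710433 to 115715072), had a log2 fold change of -4.62 ± 0.15 (edgeR adjusted p = 3.87e-18), and Ccr7, the lymph node homing receptor (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), one of -5.98 ± 0.17 (edgeR adjusted p = 2.25e-19).

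Of the residency genes, 31 of 33 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 2.35e-62 up). They include Litaf (4.43 ± 0.15) and Sik1 (3.81 ± 0.13), and Xcl1, a chemokine for cross-presenting dendritic cells, at 36.2 ± 11.0 to 147 ± 11.0 CPM in FRT and LP TRM and 0.121 ± 0.105 in TEM. Of the circulation genes, 1 of 25 rose, 21 fell and 3 did not pass (the same adjusted over the list alone, camera adjusted p = 3.49e-40 down), with Sidt1 at -3.88 ± 0.12 and Rasgrp2, an activator of the integrin switch Rap, at -2.93 ± 0.10. Of the immediate early genes, which activation and tissue digestion both induce, 32 of 34 rose, 1 fell and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 2.52e-53 up). Nr4a1, a nuclear receptor induced by receptor signals, had 5.01 ± 0.14, and Fosl2, a subunit of AP-1, 5.84 ± 0.17. The residency and immediate early lists share 3 genes. Of the heat shock genes, 12 of 13 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 5.08e-09 up), with the chaperone gene Hspa1a, whose near-identical copy Hspa1b can share its reads, at 4.91 ± 0.26. Against TEM alone, 10 of these 13 rose in FRT, 5 in IEL and 12 in LP TRM.

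Genes of other lists were called as well. Of the cytotoxic and NK receptor genes, 12 of 20 rose, 5 fell and 3 did not pass (13 higher and 7 lower adjusted over the list alone, camera adjusted p = 2.30e-05 up), with Gzmk, a granzyme, at 4.47 ± 0.21 and Fasl, a death ligand, at 3.08 ± 0.14, while Klrk1, which encodes NKG2D, stood at -2.89 ± 0.21. Of the cytokine and chemokine genes, 15 of 20 rose, 3 fell and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 3.86e-10 up, adjusted p = 0.0634 with an estimated correlation). Of the Th1 genes, 15 of 20 rose, 3 fell and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 5.97e-10 up, adjusted p = 0.118 with an estimated correlation), with Bhlhe40, a transcription factor of cytokine production, at 4.56 ± 0.23. Of the TGF-beta response genes, 11 of 17 rose and 6 did not pass (the same adjusted over the list alone, camera adjusted p = 7.67e-07 up), with Skil, an inhibitor that the pathway induces, at 2.58 ± 0.12. Of the follicular helper genes, 6 of 18 rose, 10 fell and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 4.55e-10 down), with Cxcr5, the receptor for B cell follicles, at -4.80 ± 0.14 and Tcf7, the transcription factor of memory self-renewal, at -2.31 ± 0.14. Of the lipid uptake and oxidation genes, 17 of 20 rose, 1 fell and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 4.56e-04 up). Of the cell cycle genes, 19 of 30 rose, 1 fell and 10 did not pass (20 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00165 up). Among the genes of highest fold change, Pigr, the epithelial carrier of secreted antibody, stood at 779.7 ± 47.9 CPM in IEL TRM and 1.84 ± 1.03 in TEM. Wfikkn2, an inhibitor of growth factors of the TGF-beta family, fell to 0.789 ± 0.848 CPM in IEL TRM from 155 ± 38.4 in TCM.

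Markers of other cell types moved with these groups. Of the intestinal epithelium markers, 24 of 25 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 3.77e-46 up). Of the FRT epithelium markers, 12 of 17 rose and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 9.79e-21 up). The intestinal markers summed to 415 to 1441 CPM of total counts in FRT TRM, 9219 to 9694 in IEL TRM and 2425 to 2475 in LP TRM, and to 38.6 to 49.1 in TEM. The comparison called 7835 of 17134 genes, 4245 higher and 3590 lower, and 2343 when libraries that lie as close as repeats of 1 sample were summed, a setting chosen after the data were seen. TEM libraries counted 39.2 to 45.4% of 1090 olfactory receptor genes, which T cells do not use, against 1.10 to 1.83% in TCM and splenic TRM.

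**Figure D2:**
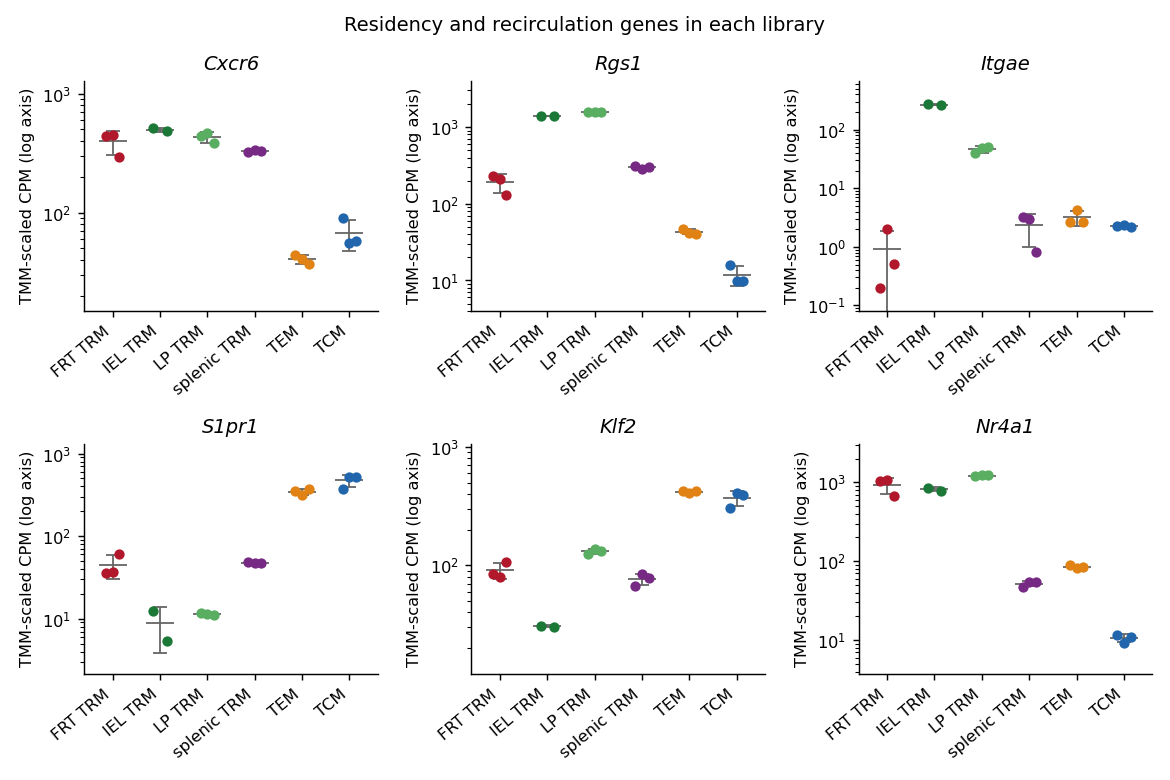
TMM-scaled CPM (log axis) of Cxcr6, Rgs1, Itgae, S1pr1, Klf2 and Nr4a1 in each of the 17 libraries, by group, with the mean and SD as a line and bars, which leave the axis where the SD exceeds the mean. Mean Cxcr6 was 328 CPM in splenic TRM and 40.6 in TEM, and mean S1pr1 was 47.9 in splenic TRM and 472 in TCM.

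Against TCM alone, residency and immediate early genes again stood higher in the mucosa and circulation genes lower. Nr4a1 rose by 6.52 ± 0.21 on the log2 scale (edgeR adjusted p = 8.49e-18), and Egr1, a transcription factor of early activation, by 4.46 ± 0.17. Ifng, the main Th1 cytokine, stood at 416 ± 191, 264 ± 4.35 and 783 ± 18.0 CPM in FRT, IEL and LP TRM and 14.3 ± 6.16 in TCM (4.96 ± 0.33, edgeR adjusted p = 4.46e-10). Ctla4, an inhibitory receptor, rose by 4.59 ± 0.28, and Tigit, another, by 3.46 ± 0.33. Ccr7 and S1pr1 had log2 fold changes of -6.48 ± 0.18 and -4.84 ± 0.16.

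Among the residency genes, 29 of 33 rose, 2 fell and 2 did not pass (30 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.51e-57 up). Among the circulation genes, 1 of 25 rose, 20 fell and 4 did not pass (1 higher and 21 lower adjusted over the list alone, camera adjusted p = 2.89e-52 down). Among the immediate early genes, 32 of 34 rose, 1 fell and 1 did not pass (33 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.85e-68 up). Of the Th17 and type 3 genes, 7 of 9 rose and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 6.79e-05 up), with Ahr, a receptor for dietary and microbial ligands, at 4.73 ± 0.28 and Tmem176a, a membrane protein gene of type 3 cells, at 3.65 ± 0.38 (97.6 ± 1.32 CPM in FRT, 3.25 ± 2.36 in IEL and 7.63 ± 1.55 in LP TRM). Among the heat shock genes, 12 of 13 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 3.03e-10 up). Ly6c2, a surface marker of effector and memory T cells, stood at -2.87 ± 0.14 over the mean of the tissues, with 6.88 ± 0.0870 and 7.97 ± 1.51 CPM in IEL and LP TRM but 201 ± 35.9 in FRT TRM, against 164 ± 42.0 in TCM. Of the stroma markers, 14 of 20 rose and 6 did not pass (15 higher adjusted over the list alone, camera adjusted p = 6.51e-10 up), and they summed to 3364 to 4384 CPM of total counts in FRT TRM against 4.14 to 5.05 in TCM. The comparison called 6239 of 17134 genes, 3584 higher and 2655 lower, and 1989 with close libraries summed.

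In the reproductive tract, residency and immediate early genes stood higher than in splenic TEM and circulation genes lower. Atf3, a stress and activation transcription factor, rose by 6.95 ± 0.25 on the log2 scale (edgeR adjusted p = 2.26e-16) and Fosl2 by 5.39 ± 0.22. Gzmb, the granzyme of cytotoxic cells (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), stood at 146 ± 71.3 CPM against 5.98 ± 1.34 (4.63 ± 0.41, edgeR adjusted p = 1.80e-07). Ccr2, a receptor for monocyte chemokines, rose by 2.57 ± 0.20. Ccr7 fell to 1.64 ± 1.06 CPM from 66.2 ± 5.0 and Klf2, the transcription factor that drives S1pr1, had -2.22 ± 0.15.

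For the residency genes, 25 of 33 rose, 3 fell and 5 did not pass (27 higher and 3 lower adjusted over the list alone, camera adjusted p = 4.72e-22 up). For the circulation genes, 3 of 25 rose, 16 fell and 6 did not pass (3 higher and 17 lower adjusted over the list alone, camera adjusted p = 1.80e-17 down). For the immediate early genes, 24 of 34 rose, 2 fell and 8 did not pass (25 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.98e-17 up). Of the regulatory T cell genes, 8 of 13 rose and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00177 up), among them Il2ra, the alpha chain of the IL-2 receptor, at 2.68 ± 0.29 and Tnfrsf4, a costimulatory receptor, at 2.72 ± 0.30. Among the cell cycle genes, 21 of 30 rose and 9 did not pass (22 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.97e-04 up), with Top2a, a topoisomerase of dividing cells, at 3.39 ± 0.22. Of the glycolysis genes, 13 of 19 rose, 1 fell and 5 did not pass (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00709 up, adjusted p = 0.227 with an estimated correlation), with Hk2, a hexokinase, at 3.54 ± 0.40, and Slc2a3, a glucose transporter, at 2.08 ± 0.17. Of the interferon-stimulated genes, 12 of 24 rose, 2 fell and 10 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0104 up, adjusted p = 0.251 with an estimated correlation), with Isg15 at 2.41 ± 0.24 and Ifit3 at 2.87 ± 0.33.

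Genes of tissue cells were among those that rose most. Among the stroma markers, 20 of 20 rose (the same adjusted over the list alone, camera adjusted p = 8.85e-40 up), with the collagen gene Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) at 624 ± 58.1 CPM against 2.62 ± 0.393 in TEM. Among the FRT epithelium markers, 17 of 17 rose (the same adjusted over the list alone, camera adjusted p = 8.85e-40 up), with Esr1, the oestrogen receptor, at 5.79 ± 0.24. Of the endothelium markers, 9 of 10 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 4.43e-04 up, adjusted p = 0.265 with an estimated correlation). Of the myeloid markers, 10 of 15 rose and 5 did not pass (11 higher adjusted over the list alone, camera adjusted p = 0.0133 up, adjusted p = 0.291 with an estimated correlation). Of the erythroid and platelet markers, 5 of 6 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0186 up, adjusted p = 0.291 with an estimated correlation). Hbb-bt, a beta globin, was at least 168-fold higher than in TEM, where no library counted it (3 counts per library as the floor). Cd24a stood at 183 ± 7.39 CPM in FRT TRM and 0.118 ± 0.205 in TEM. The comparison called 7831 of 17134 genes, 4515 higher and 3316 lower, and 1427 with close libraries summed. FRT replicate 3 held 39.0% mitochondrial rRNA and counted 13.4% of olfactory receptor genes, against 22.9 to 24.0% and 1.56 to 1.65% in replicates 1 and 2.

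Resident cells of the intestinal epithelium held more mRNA of Itgae, Ccr9 and cytotoxic genes than TEM. Itgae, which encodes the CD103 integrin that binds epithelial E-cadherin (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), stood at 268 ± 4.0 CPM against 3.18 ± 0.945 in TEM, a log2 fold change of 6.39 ± 0.29 (edgeR adjusted p = 4.46e-14). Ccr9, the small intestine homing receptor (ENSMUSG00000029530, chromosome 9, 123678439 to 123784330), stood at 425 ± 0.136 against 6.71 ± 1.06 (5.98 ± 0.23). Gzma, a granzyme, rose by 7.06 ± 0.35, Cd160, a receptor of intraepithelial lymphocytes, by 4.89 ± 0.23, and Ccl5, an inflammatory chemokine, by 2.97 ± 0.25. S1pr1 had -5.26 ± 0.29, Ccr7 -6.37 ± 0.34 and Klf2 -3.77 ± 0.20. Il6ra, the IL-6 receptor chain, stood at 0.379 ± 0.536 CPM against 184 ± 14.4.

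Of the residency genes, 31 of 33 rose, 1 fell and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 5.44e-51 up). Of the circulation genes, 1 of 25 rose, 19 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 4.38e-23 down). Among the TGF-beta response genes, 10 of 17 rose and 7 did not pass (11 higher adjusted over the list alone, camera adjusted p = 2.81e-08 up), with Pmepa1, a feedback inhibitor of the pathway, at 6.26 ± 0.37 and Smad7, another, at 1.79 ± 0.17. Among the cytotoxic and NK receptor genes, 11 of 20 rose, 4 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 1.20e-07 up). Of the homing receptors, 9 of 23 rose, 7 fell and 7 did not pass (10 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.212 up). The circulation and homing lists share 5 genes. Of the aryl hydrocarbon receptor targets, 3 of 6 rose and 3 did not pass (4 higher adjusted over the list alone, camera adjusted p = 0.00563 up, adjusted p = 0.142 with an estimated correlation), with Tiparp at 1.33 ± 0.22. Of the immediate early genes, 26 of 34 rose, 2 fell and 6 did not pass (27 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.21e-17 up), with Egr1 at 4.42 ± 0.18. Of the CD8, NK and gamma-delta T cell markers, 6 of 9 rose and 3 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0180 up, adjusted p = 0.113 with an estimated correlation), with Cd8a at 4.95 ± 0.85 and 19.3 ± 4.58 CPM.

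Among the lipid uptake and oxidation genes, 14 of 20 rose, 1 fell and 5 did not pass (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.46e-12 up). Its members Fabp1 and Fabp2, lipid carriers of enterocytes, stood at 411 ± 6.34 and 731 ± 8.38 CPM against 0.0591 ± 0.102 and 0.247 ± 0.429, and Slc27a4, a fatty acid transporter, had 3.62 ± 0.21. Epithelium markers moved with that list. Among the intestinal epithelium markers, 25 of 25 rose (the same adjusted over the list alone, camera adjusted p = 3.13e-108 up), with Apoa1, an apolipoprotein of enterocytes and liver (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), at 2181 ± 42.3 CPM against 0.487 ± 0.570 and Mttp, which loads lipoproteins, at 7.33 ± 0.22. Spink1, a trypsin inhibitor, was at least 122-fold higher than in TEM, where no library counted it. The comparison called 6747 of 17134 genes, 3400 higher and 3347 lower, and 610 with close libraries summed. Without IEL replicate 1 it called 4262 and without replicate 2 4206, where the lone library is assumed to vary like the other groups.

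Lamina propria TRM, compared with TEM, held more mRNA of residency, immediate early and heat shock genes. Ahr stood at 133 ± 9.02 CPM against 3.92 ± 0.639 (log2 fold change 5.07 ± 0.25, edgeR adjusted p = 3.06e-14). Ccr9 stood at 386 ± 20.6 against 6.71 ± 1.06 (5.84 ± 0.23) and Itgae at 46.7 ± 6.36 (3.87 ± 0.28). Hspa1a, an inducible chaperone (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156), stood at 666 ± 13.5 CPM against 13.8 ± 3.72 (5.60 ± 0.34). Icos, a costimulatory receptor, rose by 2.59 ± 0.24, and Bcl6, the transcription factor of follicular helper cells, by 2.47 ± 0.18.

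Among the residency genes, 31 of 33 rose, 1 fell and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 1.21e-60 up). Among the circulation genes, 3 of 25 rose, 16 fell and 6 did not pass (3 higher and 17 lower adjusted over the list alone, camera adjusted p = 9.59e-23 down). For the heat shock genes, 12 of 13 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 1.42e-13 up). Among the immediate early genes, 28 of 34 rose, 2 fell and 4 did not pass (28 higher and 3 lower adjusted over the list alone, camera adjusted p = 8.77e-31 up), with Nr4a3 at 5.92 ± 0.32. Of the inhibitory and costimulatory genes, 16 of 20 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 1.64e-06 up, adjusted p = 0.166 with an estimated correlation), with Pdcd1lg2, a ligand of PD-1, at 4.28 ± 0.36. For the cytotoxic and NK receptor genes, 11 of 20 rose, 4 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 1.21e-07 up), with Gzmb at 6.35 ± 0.42. For the cell cycle genes, 17 of 30 rose and 13 did not pass (the same adjusted over the list alone, camera adjusted p = 2.53e-04 up), with Mki67, a proliferation marker, at 3.27 ± 0.53. Among the Th17 and type 3 genes, 6 of 9 rose, 2 fell and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00138 up).

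Of the B and plasma cell markers, 3 of 12 rose, 2 fell and 7 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0330 up, adjusted p = 0.306 with an estimated correlation, median log2 fold change -0.29 against a mean of 1.06), with Igha, the IgA heavy chain, at 531 ± 15.7 CPM against 0.712 ± 0.156 (9.49 ± 0.40). For the intestinal epithelium markers, 25 of 25 rose (the same adjusted over the list alone, camera adjusted p = 3.29e-74 up). Defa24, a Paneth cell defensin with near-identical copies (ENSMUSG00000064213, chromosome 8, 21734494 to 21735471), stood at 1072 ± 29.0 CPM and was at least 1998-fold higher than in TEM, where no library counted it. Aff3 fell by 7.24 on the log2 scale and Cmah, an enzyme of sialic acid synthesis, by 6.37. The comparison called 7018 of 17134 genes, 3388 higher and 3630 lower, and 372 with close libraries summed.

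The next comparison asked whether CD69+ cells of the spleen differ from CD69- TEM in genes tied to residency. Splenic TRM held more mRNA of several residency and inhibitory genes and less of recirculation genes. Cxcr6 stood at 328 ± 6.20 CPM against 40.6 ± 3.56 in TEM, a log2 fold change of 3.01 ± 0.20 (edgeR adjusted p = 6.01e-11). Rgs1 rose by 2.79 ± 0.20 and Prdm1, which encodes Blimp-1, by 2.04 ± 0.19. S1pr1 stood at 47.9 ± 0.274 against 346 ± 30.8 (-2.85 ± 0.20, edgeR adjusted p = 3.16e-10) and Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656) at 76.4 ± 8.41 against 418 ± 11.6 (-2.45 ± 0.15). Eomes, a T-box transcription factor of memory and cytotoxic cells (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), stood at 41.7 ± 6.66 CPM against 2.38 ± 0.505 (4.12 ± 0.46). Itgae, by contrast with the epithelium, stood at 2.33 ± 1.31 and 3.18 ± 0.945 CPM and was not called.

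For the residency genes, 21 of 33 rose, 3 fell and 9 did not pass (22 higher and 3 lower adjusted over the list alone, camera adjusted p = 7.92e-29 up). For the circulation genes, 1 of 25 rose, 16 fell and 8 did not pass (1 higher and 17 lower adjusted over the list alone, camera adjusted p = 7.19e-17 down). Among the inhibitory and costimulatory genes, 12 of 20 rose, 3 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 3.91e-13 up, adjusted p = 0.0897 with an estimated correlation), with Pdcd1, which encodes PD-1, at 2.05 ± 0.33, Tnfrsf9, a costimulatory receptor, at 3.18 ± 0.43 and Cd160 at 3.58 ± 0.22. Among the regulatory T cell genes, 6 of 13 rose, 1 fell and 6 did not pass (the same adjusted over the list alone, camera adjusted p = 5.23e-06 up), with Il2ra at 2.72 ± 0.28. Among the cytokine and chemokine genes, 9 of 20 rose and 11 did not pass (11 higher adjusted over the list alone, camera adjusted p = 3.91e-13 up, adjusted p = 0.0634 with an estimated correlation), with Ccl3 at 3.88 ± 0.53. Among the Th1 genes, 11 of 20 rose, 1 fell and 8 did not pass (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.48e-09 up, adjusted p = 0.157 with an estimated correlation). Among the homing receptors, 8 of 23 rose, 5 fell and 10 did not pass (the same adjusted over the list alone, camera adjusted p = 2.65e-04 up, adjusted p = 0.301 with an estimated correlation), with Itga1, a collagen-binding integrin, at 3.56 ± 0.29. Of the cytotoxic and NK receptor genes, 8 of 20 rose, 4 fell and 8 did not pass (the same adjusted over the list alone, camera adjusted p = 4.51e-05 up, median log2 fold change -0.12 against a mean of 0.18), with Gzmk at 3.77 ± 0.28 and Klrd1, an NK receptor chain, at -3.81 ± 0.47. For the immediate early genes, 10 of 34 rose, 4 fell and 20 did not pass (the same adjusted over the list alone, camera adjusted p = 6.05e-04 up, adjusted p = 0.308 with an estimated correlation). Cd69 itself had 0.43 ± 0.20 and was not called (edgeR adjusted p = 0.121), though it was called with the compared groups fitted alone (0.41) and with limma-voom (0.43).

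Among the genes of highest fold change were Mmp9, a matrix protease (5.56 ± 0.36), Csf1, the macrophage growth factor (5.17 ± 0.35), Atp8a2, a lipid flippase (4.81 ± 0.20), and Fgl2, a secreted inhibitor of immune cells (4.66 ± 0.35). Fcgr2b, the inhibitory Fc receptor, stood at 0.443 ± 0.339 CPM against 11.3 ± 2.40. For the stroma markers, 12 of 20 fell and 8 did not pass (13 lower adjusted over the list alone, camera adjusted p = 6.11e-08 down, adjusted p = 0.0897 with an estimated correlation), with Col1a1 at 2.62 ± 0.393 CPM in TEM and 0.118 ± 0.205 in splenic TRM. Olfactory receptor genes with a count made up 39.2 to 45.4% of that family in TEM and 1.47 to 1.83% in splenic TRM. The comparison called 4275 of 17134 genes, 1255 higher and 3020 lower. With protein-coding genes alone, the split was 601 higher and 3723 lower, and fitted on its own libraries alone 2092 and 2559. Limma-voom called 6513. With close libraries summed, edgeR called 0 genes, and 1772 passed an unadjusted p under 0.05.

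Compared with TCM, splenic TRM held more mRNA of immediate early, cytokine and chemokine, and inhibitory and costimulatory genes. Rgs1 stood at 300.2 ± 12.8 CPM against 11.9 ± 3.49 in TCM (log2 fold change 4.63 ± 0.23, edgeR adjusted p = 4.09e-13), Ifng at 164 ± 3.87 against 14.3 ± 6.16 (3.53 ± 0.33) and Gzmb at 89.2 ± 4.71 against 4.6 ± 3.82 (4.21 ± 0.44). Id2, a regulator of effector differentiation, rose by 2.04 ± 0.15. Ly6c2 had -3.20 ± 0.19, S1pr1 -3.30 ± 0.21 and Ccr7 -2.65 ± 0.18. Atp8a2 (6.79 ± 0.28) and Xcl1, at 21.6 ± 4.53 CPM and at least 25-fold above TCM, where no library counted it, were among the genes of highest fold change.

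Of the residency genes, 21 of 33 rose, 2 fell and 10 did not pass (22 higher and 4 lower adjusted over the list alone, camera adjusted p = 1.19e-53 up). Of the circulation genes, 1 of 25 rose, 18 fell and 6 did not pass (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 3.37e-43 down). Of the immediate early genes, 29 of 34 rose and 5 did not pass (31 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.41e-68 up), with Tnfaip3, an inhibitor of NF-kappaB signals, at 3.16 ± 0.28 and Ppp1r15a, a stress response gene, at 2.52 ± 0.22. For the cytokine and chemokine genes, 10 of 20 rose and 10 did not pass (16 higher adjusted over the list alone, camera adjusted p = 3.52e-23 up). For the inhibitory and costimulatory genes, 11 of 20 rose, 1 fell and 8 did not pass (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.80e-16 up), with Ctla4 at 3.47 ± 0.29 and Tigit at 2.65 ± 0.35. For the regulatory T cell genes, 6 of 13 rose, 1 fell and 6 did not pass (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.91e-07 up). The comparison called 1444 of 17134 genes, 809 higher and 635 lower, and 14 with close libraries summed. It called 854 and 880 without TCM replicate 5 or 6, 2573 without FRT replicate 3, which enters through the shared estimate of the spread, and 2806 without it and TCM replicate 3. Fitted on its own libraries it called 2463, and limma-voom 3785.

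Among circulating cells, TEM held more mRNA of immediate early genes than TCM, and less of the lymphoid homing receptor Ccr7. Klf4, a transcription factor of T cell quiescence, stood at 32.7 ± 0.998 CPM against 2.55 ± 0.958 (log2 fold change 3.70 ± 0.29, edgeR adjusted p = 4.35e-09), and Nr4a1 rose by 3.00 ± 0.20. Ifng stood at 132 ± 12.2 against 14.3 ± 6.16 (3.22 ± 0.33) and Ctla4 had 2.29 ± 0.31. Ccr7 fell to 66.2 ± 5.0 CPM from 134 ± 31.5 (-1.01 ± 0.17). Ly6c2 had -1.57 ± 0.17. Rpph1, the RNA of RNase P, stood at 428 ± 18.4 CPM in TEM and 2004 ± 574 in TCM. Genes of the rRNA class held 0.714 to 0.891% of counts in TEM and 3.35 to 6.14% in TCM, and lincRNA 2.89 to 2.95% and 2.49 to 5.93%. The library labelled TCM replicate 3 had 97.3 CPM of Ccr7 and 7.35 of Ifng, against 151 to 152 and 16.8 to 18.9 in replicates 5 and 6.

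Among the immediate early genes, 27 of 34 rose and 7 did not pass (the same adjusted over the list alone, camera adjusted p = 3.01e-29 up), with Junb, a subunit of AP-1, at 2.33 ± 0.24 and Zfp36, which destabilises cytokine mRNA, at 1.44 ± 0.15. Among the residency genes, 9 of 33 rose, 3 fell and 21 did not pass (9 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.128 up), with Rgs1 at 1.84 ± 0.22 and Sik1 at 2.85 ± 0.22. Among the circulation genes, 2 of 25 rose, 6 fell and 17 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0436 down, adjusted p = 0.562 with an estimated correlation). For the homing receptors, 1 of 23 rose, 7 fell and 15 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00193 down, adjusted p = 0.681 with an estimated correlation). Among the glycolysis genes, 6 of 19 fell and 13 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00415 down, adjusted p = 0.422 with an estimated correlation), with Pgk1 at -1.30 ± 0.26. Of the genes of the sorting gates, 1 of 7 rose, 2 fell and 4 did not pass (the same adjusted over the list alone, camera adjusted p = 0.503 down). Of the stroma markers, 11 of 20 rose and 9 did not pass (12 higher adjusted over the list alone, camera adjusted p = 8.18e-05 up, adjusted p = 0.422 with an estimated correlation), and TEM libraries counted 39.2 to 45.4% of olfactory receptor genes against 1.10 to 1.56% in TCM. The comparison called 4213 of 17134 genes, 2816 higher and 1397 lower. It called 3600 higher and 498 lower among protein-coding genes alone, 7060 with limma-voom and 2163 and 2189 without TCM replicate 5 or 6. With close libraries summed, edgeR called 0, and 1919 passed an unadjusted p under 0.05.

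Between resident cells of mucosa and spleen, the immediate early and residency genes stood higher in the mucosa and follicular helper genes stood lower. Nr4a1 rose by 4.23 ± 0.18 on the log2 scale (edgeR adjusted p = 2.09e-15), with 930.1 ± 219, 822 ± 52.0 and 1217 ± 21.8 CPM in FRT, IEL and LP TRM against 52.1 ± 4.09. Ahr stood at 19.8 ± 2.48, 69.4 ± 8.15 and 133 ± 9.02 against 2.89 ± 1.07 (4.32 ± 0.24). Litaf had 3.74 ± 0.19 and Gzmb 1.87 ± 0.29. Cxcr5 (ENSMUSG00000047880, chromosome 9, 44511787 to 44561877) stood at 73.6 ± 3.35 CPM in splenic TRM and 2.24 ± 0.484 in IEL TRM (-4.22 ± 0.15, edgeR adjusted p = 1.59e-16), Izumo1r, the folate receptor 4 of follicular helper and regulatory cells, had -3.62 ± 0.25 and Eomes -2.02 ± 0.30.

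For the residency genes, 23 of 33 rose, 2 fell and 8 did not pass (the same adjusted over the list alone, camera adjusted p = 8.23e-22 up). For the circulation genes, 1 of 25 rose, 14 fell and 10 did not pass (2 higher and 14 lower adjusted over the list alone, camera adjusted p = 6.73e-15 down). For the immediate early genes, 27 of 34 rose, 1 fell and 6 did not pass (28 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.60e-25 up). Of the heat shock genes, 11 of 13 rose and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 9.68e-06 up, adjusted p = 0.124 with an estimated correlation). Among the follicular helper genes, 3 of 18 rose, 11 fell and 4 did not pass (the same adjusted over the list alone, camera adjusted p = 2.51e-18 down). For the TGF-beta response genes, 9 of 17 rose, 1 fell and 7 did not pass (the same adjusted over the list alone, camera adjusted p = 9.68e-06 up), with Tgif1 at 2.44 ± 0.14. Among the aryl hydrocarbon receptor targets, 4 of 6 rose and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 2.08e-04 up). Of the cell cycle genes, 20 of 30 rose and 10 did not pass (23 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.10e-05 up), with Kif11, a motor of the spindle, at 2.70 ± 0.35. For the lipid uptake and oxidation genes, 13 of 20 rose and 7 did not pass (the same adjusted over the list alone, camera adjusted p = 3.60e-05 up). Cd22, an inhibitory lectin of B cells, stood at 39.7 ± 4.17 CPM in splenic TRM and 0.797 ± 0.489 in LP TRM (-5.13 ± 0.27). Of the intestinal epithelium markers, 24 of 25 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 6.33e-66 up). Among the stroma markers, 15 of 20 rose and 5 did not pass (16 higher adjusted over the list alone, camera adjusted p = 8.77e-14 up). The comparison called 5607 of 17134 genes, 3258 higher and 2349 lower, and 828 with close libraries summed.

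FRT TRM held less mRNA of residency, TGF-beta response and cytotoxic genes than LP TRM. Residency sums were 7613, 7557 and 2870 CPM in FRT replicates 1 to 3 (LP 11070 to 11340). Itgae stood at 0.909 ± 0.973 CPM against 46.7 ± 6.36 (log2 fold change -5.51 ± 0.37, edgeR adjusted p = 1.04e-10), Ccr9 at 33.0 ± 13.5 against 386 ± 20.6 (-3.48 ± 0.20) and Rgs1 at 189 ± 52.6 against 1567 ± 21.6 (-3.04 ± 0.20). Gpr55, a lipid receptor, had -2.04 ± 0.17 and Cd160 -4.46 ± 0.23. Higher in FRT TRM were Ly6c2, at 201 ± 35.9 CPM against 7.97 ± 1.51 (4.64 ± 0.21), Nrp1, a coreceptor of regulatory T cells (3.13 ± 0.27), and Ccr2 (1.78 ± 0.19).

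Of the residency genes, 21 of 33 fell and 12 did not pass (23 lower adjusted over the list alone, camera adjusted p = 2.17e-15 down). Of the TGF-beta response genes, 2 of 17 rose, 10 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 2.12e-04 down), with Smurf2 at -1.29 ± 0.12. Among the cytotoxic and NK receptor genes, 2 of 20 rose, 10 fell and 8 did not pass (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 5.54e-06 down), with Gzma at -5.77 ± 0.40. Among the heat shock genes, 1 of 13 rose, 11 fell and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 1.36e-06 down, adjusted p = 0.148 with an estimated correlation), with Hsph1 at -1.46 ± 0.17. Tissue markers moved too, and T cell content was not tested as a cause, here or against IEL TRM. For the stroma markers, 20 of 20 rose (the same adjusted over the list alone, camera adjusted p = 2.40e-41 up), with sums of 3364 to 4384 CPM in FRT and 149 to 176 in LP TRM, and of the intestinal epithelium markers, 2 of 25 rose, 18 fell and 5 did not pass (3 higher and 18 lower adjusted over the list alone, camera adjusted p = 1.94e-30 down). Itln1, an intestinal lectin at 123 ± 14.7 CPM in LP TRM, was at least 134-fold lower in FRT TRM, where no library counted it. The comparison called 5869 of 17134 genes, 3492 higher and 2377 lower, and 480 with close libraries summed. Fitted on its own libraries it called 3645.

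Within the small intestine, IEL TRM held more mRNA of Itgae and less of heat shock genes than LP TRM. Itgae stood at 268 ± 4.0 CPM against 46.7 ± 6.36 (log2 fold change 2.52 ± 0.23, edgeR adjusted p = 2.88e-08). Hspa1a stood at 84.8 ± 18.1 against 666 ± 13.5 (-2.97 ± 0.35), Ifng at 264 ± 4.35 against 783 ± 18.0 (-1.57 ± 0.32) and Tnf, an inflammatory cytokine, had -1.22 ± 0.16. Icos (-1.60 ± 0.26) and Tnfrsf4 (-2.13 ± 0.34) stood lower, as did Klf2 (-2.10 ± 0.18). Gzma (1.91 ± 0.25) and Egr1 (1.94 ± 0.17) stood higher.

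For the heat shock genes, 11 of 13 fell and 2 did not pass (13 lower adjusted over the list alone, camera adjusted p = 1.88e-15 down). Of the immediate early genes, 5 of 34 rose, 16 fell and 13 did not pass (5 higher and 20 lower adjusted over the list alone, camera adjusted p = 1.60e-04 down, adjusted p = 0.271 with an estimated correlation). For the Th1 genes, 7 of 20 fell and 13 did not pass (10 lower adjusted over the list alone, camera adjusted p = 0.00133 down, adjusted p = 0.453 with an estimated correlation). Of the regulatory T cell genes, 4 of 13 fell and 9 did not pass (the same adjusted over the list alone, camera adjusted p = 0.010 down, adjusted p = 0.0595 with an estimated correlation). Among the cell cycle genes, 5 of 30 fell and 25 did not pass (the same adjusted over the list alone, camera adjusted p = 9.03e-04 down). For the glycolysis genes, 7 of 19 rose, 1 fell and 11 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00525 up, adjusted p = 0.210 with an estimated correlation). Of the lipid uptake and oxidation genes, 10 of 20 rose, 2 fell and 8 did not pass (the same adjusted over the list alone, camera adjusted p = 8.49e-11 up), with Cpt2, which imports fatty acids into mitochondria, at 2.06 ± 0.28. Epithelium markers moved with the lipid genes. Among the intestinal epithelium markers, 19 of 25 rose, 2 fell and 4 did not pass (21 higher and 3 lower adjusted over the list alone, camera adjusted p = 5.78e-39 up), where Apoa4 stood at 1993 ± 236 CPM against 14.8 ± 3.91 and the Paneth cell gene Defa24 at 13.8 ± 0.722 against 1072 ± 29.0. Among the B and plasma cell markers, 3 of 12 fell and 9 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00373 down, adjusted p = 0.246 with an estimated correlation, median log2 fold change 0.14 against a mean of -0.43). Of the stroma markers, 1 of 20 rose, 14 fell and 5 did not pass (1 higher and 17 lower adjusted over the list alone, camera adjusted p = 2.10e-17 down). Among the CD8, NK and gamma-delta T cell markers, 4 of 9 rose and 5 did not pass (6 higher adjusted over the list alone, camera adjusted p = 0.0156 up, adjusted p = 0.136 with an estimated correlation). The comparison called 2507 of 17134 genes, 1389 higher and 1118 lower, and 31 with close libraries summed. It called 1289 without IEL replicate 1, 1168 without replicate 2, 4033 without FRT replicate 3, 4464 without it and TCM replicate 3, 4101 on its own libraries and 3801 with limma-voom.

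FRT TRM held less mRNA of Itgae and of cytotoxic genes and more of regulatory T cell and cell cycle genes than IEL TRM. Itgae stood at 0.909 ± 0.973 CPM against 268 ± 4.0 (log2 fold change -8.03 ± 0.36, edgeR adjusted p = 5.09e-14) and Cd160 at 4.96 ± 1.64 against 158 ± 14 (-4.87 ± 0.24). Prf1, which encodes perforin, had -2.64 ± 0.40. Nrp1 (5.57 ± 0.41), Cxcr4, a receptor for stromal CXCL12 (3.14 ± 0.28), Il21, a cytokine for B cells (4.02 ± 0.72), and Klrk1 (4.40 ± 0.46) stood higher in FRT TRM.

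For the cytotoxic and NK receptor genes, 1 of 20 rose, 11 fell and 8 did not pass (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 7.29e-06 down). Among the TGF-beta response genes, 3 of 17 rose, 7 fell and 7 did not pass (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00214 down, median log2 fold change -0.47 against a mean of 0.15). Among the residency genes, 3 of 33 rose, 18 fell and 12 did not pass (3 higher and 19 lower adjusted over the list alone, camera adjusted p = 8.91e-10 down, adjusted p = 0.0624 with an estimated correlation), with P2rx7, a receptor for extracellular ATP, at -2.13 ± 0.15. Among the regulatory T cell genes, 5 of 13 rose, 1 fell and 7 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00436 up). For the cell cycle genes, 9 of 30 rose and 21 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00463 up). For the follicular helper genes, 8 of 18 rose, 1 fell and 9 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0149 up, adjusted p = 0.421 with an estimated correlation). Of the lipid genes, 3 of 20 rose, 8 fell and 9 did not pass (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 4.15e-08 down). Among the stroma markers, 19 of 20 rose and 1 did not pass (the same adjusted over the list alone, camera adjusted p = 2.38e-50 up). For the intestinal epithelium markers, 1 of 25 rose, 22 fell and 2 did not pass (the same adjusted over the list alone, camera adjusted p = 1.23e-70 down), with Mttp at -7.15 ± 0.23. Reg3b, an antibacterial lectin at 136 ± 20.4 CPM in IEL TRM, was at least 149-fold lower in FRT TRM, where no library counted it. The comparison called 5308 of 17134 genes, 2982 higher and 2326 lower, and 1037 with close libraries summed. It called 3420 and 3116 without IEL replicate 1 or 2 and 2689 on its own libraries.

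**Figure D3:**
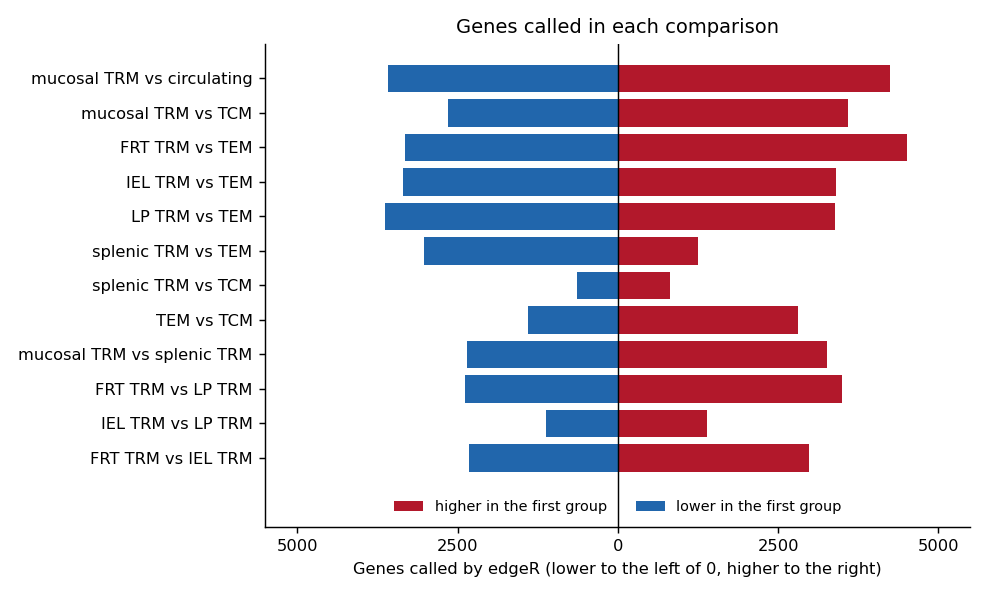
Bars give the number of genes that edgeR called in each of the 12 comparisons, higher in the first group to the right of 0 and lower to the left. The numbers run from 1444 genes between splenic TRM and TCM to 7835 between mucosal TRM and circulating cells.

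Genes called the same way in each of FRT, IEL and LP TRM against both TEM and TCM numbered 1008 higher and 464 lower. The lowest mean log2 fold changes over the 6 contrasts were those of Dapl1 (-7.27) and Tdrp (-6.87). Il6ra had a mean of -6.67, Ccr7 of -5.98, Cxcr5 of -4.80, S1pr1 of -4.62 and Nsg2, a gene of vesicle traffic, of -5.57. Of the 1008 higher genes, 324 were called higher and 185 lower in splenic TRM against TEM, and of the 464 lower ones, 218 were called lower and 3 higher. Against TCM, the calls were 272 higher and 15 lower of the first and 157 lower and 5 higher of the second. Among the named ones, against TEM, S1pr1 (-2.85 ± 0.20), Ccr7 (-1.64 ± 0.18), Nsg2 (-0.84 ± 0.14) and Il6ra (-1.48 ± 0.16) also fell, and Cxcr5 did not pass (-0.23 ± 0.16, edgeR adjusted p = 0.301) but fell against TCM (-0.94 ± 0.16, edgeR adjusted p = 1.78e-04). Among the genes of highest fold change, Xcl1 stood out from epithelial genes. It had 21.6 ± 4.53 CPM in splenic TRM as well, whereas Krt8, a keratin of simple epithelia, had 0.0544 ± 0.0943, Pigr 0.109 ± 0.189 and Cldn3, a tight junction protein, no count there. The other named higher genes, Clca1, Krt19, Prap1, Elf3, Tspan8, Anpep and Klf5, are known from epithelia, and epithelium markers summed to 415 to 1441 CPM even in FRT TRM. Lists of the same sizes drawn independently would share 58.8 higher and 9.70 lower genes. Part of the excess may come from the TEM and TCM libraries that all contrasts share. With close libraries summed, 179 genes met the rule, 150 higher and 29 lower.

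A last question was whether splenic TRM differ from TEM along the genes that mark mucosal TRM against TCM, a set defined on libraries that do not enter the tested contrast. Of the 2655 genes lower in mucosal TRM, 63.6% were also lower in splenic TRM than in TEM, 477 of them called lower and 107 called higher (fry adjusted p = 2.24e-05 downward). S1pr1, Klf2, Ccr7 and Sidt1, which had -2.49 ± 0.17 here, are circulation genes within that set. Of the 3584 genes higher in mucosal TRM, 44.5% were higher in splenic TRM, 617 called higher, among them Cxcr6 and Rgs1, and 868 called lower (fry adjusted p = 1.34e-04 downward). Fry tests against no change, and genes as a whole shifted downward in this contrast. Of all genes tested, 58.0% were lower and 41.6% higher in splenic TRM, with a median log2 fold change of -0.13, against -0.16 in the lower set and -0.13 in the higher set. Of the called genes, 81.7% of the lower set were lower, against 3020 of all 4275. Of the higher set, 41.5% were higher, against 29.4% of all. Neither downward result is set apart from the general shift by a test. The direction of the higher set turned with the genes kept and the libraries fitted. Among the 1535 of them with a mean CPM of 5 or more in TCM, a limit chosen after the data were seen, 73.2% were higher in splenic TRM (fry adjusted p = 5.88e-06 upward). With each contrast fitted on its own libraries alone, 62.6% of 2277 were higher (fry adjusted p = 3.94e-09 upward).

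**Figure D4:**
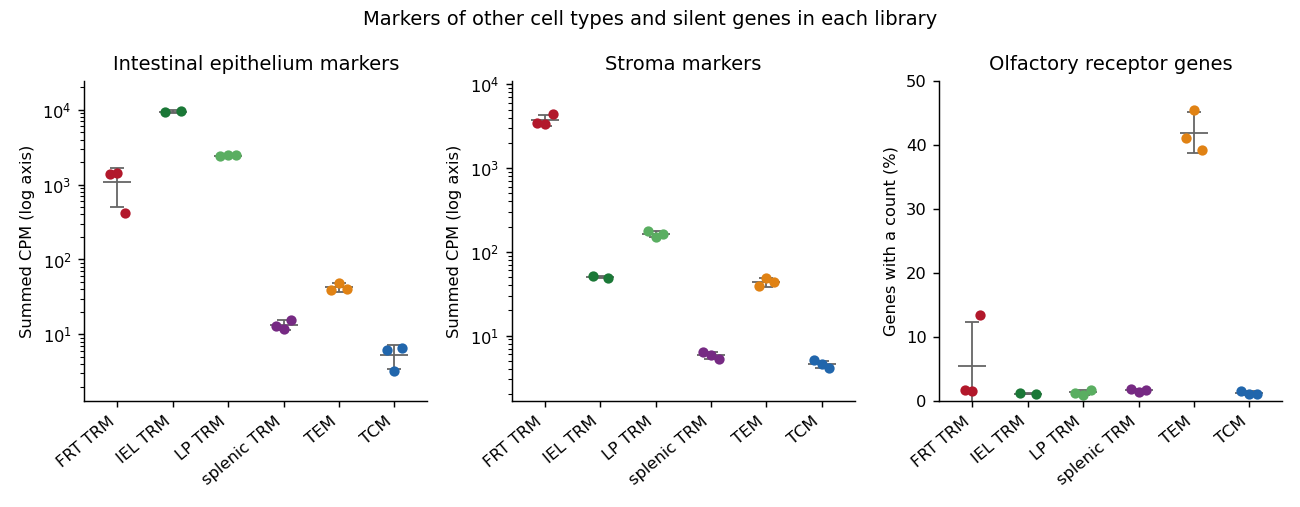
Summed CPM of total counts (log axes) of the intestinal epithelium and stroma markers, and the share of olfactory receptor genes with a count (%), in each of the 17 libraries by group, with the mean and SD as a line and bars. Intestinal epithelium markers summed to 9219 to 9694 CPM in IEL TRM, stroma markers to 3364 to 4384 in FRT TRM, and TEM libraries counted 39.2 to 45.4% of olfactory receptor genes.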

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

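The comparison of directions between tissues and the tests of this part were chosen after the result was seen. List members outside the marker and gate lists were compared where any mucosal TRM group or TEM had a mean of at least 10 CPM. Each compared group needed a mean of at least 3 counts, and each of 2 tissues a called 2-fold change against TEM. Of these genes, 6 moved one way against TEM in FRT TRM and the opposite way in LP and IEL TRM. The difference between the tissues was called by edgeR for each, which was part of this choice of genes and is no separate evidence. Itgae, the epithelial integrin, had a log2 fold change against TEM of -1.64 ± 0.52 in FRT TRM, 3.87 ± 0.28 in LP TRM and 6.39 ± 0.29 in IEL TRM. In FRT TRM it had 12 counts in all, at 0.909 ± 0.973 CPM, so that its fall there lies near the floor. The difference was -5.509 ± 0.37 between FRT and LP TRM and -8.032 ± 0.36 between FRT and IEL TRM. Ly6c2 had 1.87 ± 0.17 in FRT TRM against -2.77 ± 0.21 in LP and -3.01 ± 0.25 in IEL TRM, with differences of 4.644 ± 0.21 and 4.874 ± 0.26.

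Ier3, a stress response gene, rose in FRT TRM (3.21 ± 0.24) and fell in LP TRM (-1.30 ± 0.29) and IEL TRM (-1.04 ± 0.32), with differences of 4.505 ± 0.27 and 4.251 ± 0.32. Capg, an actin capping protein of myeloid and resident T cells, had differences of 3.542 ± 0.30 and 3.502 ± 0.35. Cd200, an inhibitory ligand, had 3.979 ± 0.70 and 4.088 ± 0.84, and Il1r1, the IL-1 receptor, 2.903 ± 0.49 and 4.864 ± 0.69. FRT TRM also held stroma markers, and whether these or other FRT differences belong to the T cells was not tested.

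Mucosal TRM libraries also held epithelial and stromal transcripts. Of the markers of these types, 45 of 45 were called higher against TEM (25 intestinal ones in IEL TRM and 20 stroma markers in FRT TRM). A background in proportion to gene length is argued against, as it would give at most 0.0805% of the marker sums. RNA from epithelial and stromal cells, captured with the sorted CD4+ CD45.1+ cells or free, stays open, since the count of markers restates the pattern. Expression by the T cells and, untested, a difference between tissues stay open too. In FRT replicate 3 the stroma markers had a median log2 ratio of 0.52 (quartiles 0.059 and 1.10) to replicates 1 and 2. Ptprc had -2.04 and Cd4 -1.94, and intestinal markers summed to 415 CPM against 1404 and 1441, but that is 1 library.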

How the results depend on the processing

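The settings that sum libraries, leave FRT replicate 3 and the library labelled TCM replicate 3 out together, subtract background, keep protein-coding genes or set a CPM limit in TCM were chosen after the data were seen. RLE scaling, DESeq2, no filter, subtracted background and protein-coding genes alone left the count of called genes of each of the 12 comparisons within 1.5 times the first value. RLE moved the median of all genes by at most 0.049 on the log2 scale. Of 193 values of named genes, 193 kept their call with RLE, 193 of 193 with DESeq2 and 113 with close libraries summed, and none reversed in any setting run. Of 116 list results, 81 kept their side with an estimated correlation.

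With close libraries summed, edgeR called 2343 genes for mucosal TRM against circulating cells, 1989 against TCM and 828 against splenic TRM. It called 1427 for FRT, 610 for IEL and 372 for LP TRM against TEM, 480 for FRT against LP, 31 for IEL against LP and 1037 for FRT against IEL TRM. For splenic TRM it called 0 against TEM (1772 at an unadjusted p under 0.05) and 14 against TCM, and for TEM against TCM 0 (1919 unadjusted). Core genes numbered 179. By construction this setting takes the spread from FRT and TCM, whose libraries stand apart, and the lone samples are assumed to vary like them.

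With limma-voom and quality weights, 6513 genes were called for splenic TRM against TEM, 3785 against TCM, 7060 for TEM against TCM and 3801 for IEL against LP TRM. With the compared groups fitted alone, 2463 were called for splenic TRM against TCM, 3645 for FRT against LP, 4101 for IEL against LP and 2689 for FRT against IEL TRM. With FRT replicate 3 and the library labelled TCM replicate 3 both left out, 2806 were called for splenic TRM against TCM and 4464 for IEL against LP TRM. For these settings the cause was not tested.

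Leaving out each library in turn, calls ran from 4206 to 8256 for IEL TRM against TEM, 1168 to 4033 for IEL against LP and 3116 to 5620 for FRT against IEL TRM, lowest each time without IEL replicate 2. They ran from 854 to 2573 for splenic TRM against TCM and 2163 to 5816 for TEM against TCM, lowest without TCM replicate 5. Each of these was highest without FRT replicate 3. A lone IEL sample is assumed to vary like the other groups. The other comparisons and the core genes stayed within 1.5 times.

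With the replicate block, over the 5 groups that share numbers, edgeR called 3973 genes for splenic TRM against TEM (768 higher and 3205 lower). The share called higher in that comparison ran from 13.9% with protein-coding genes to 45% with its own libraries alone, against 29.4% at first. Of signature genes higher in mucosal TRM, 62.6% were higher in splenic TRM with the compared groups alone, 46.0% with background subtracted and 73.2% at 5 CPM or more in TCM, against 44.5% at first. The direction by fry was up in these 3 settings (fry adjusted p = 3.94e-09, 0.0917 and 5.88e-06), so that with background subtracted the set did not pass. Over the settings that kept the downward direction, the fry adjusted p ran from 4.92e-10 to 0.0212. The set held 3584 genes at first, and 2277, 3517 and 1535 in the 3 settings, and the cause was not tested. The lower set stayed downward in each setting run, with 59.4 to 85.0% lower in splenic TRM.

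Depth limits genes with few counts. Genes under 10 CPM changed 4-fold were mostly missed in simulation, and IEL TRM has 2 libraries.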

Other observations

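Of the interferon-stimulated genes, 13 of 24 rose, 2 fell and 9 did not pass (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00567 up, adjusted p = 0.160 with an estimated correlation) between mucosal TRM and circulating cells, with Isg15, a ubiquitin-like antiviral protein, at 2.72 ± 0.16 and Isg20, an antiviral exonuclease, at 1.74 ± 0.12. Of the Th2 genes, 3 of 8 rose, 1 fell and 4 did not pass (the same adjusted over the list alone, camera adjusted p = 0.224 up), with Il4ra, the IL-4 receptor chain, at 1.93 ± 0.13. Of the glycolysis genes, 9 of 19 rose, 3 fell and 7 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0481 up, adjusted p = 0.276 with an estimated correlation), with Tpi1, a glycolytic enzyme, at 1.59 ± 0.11 and Pdk1, which diverts pyruvate from mitochondria, at -1.35 ± 0.10.

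In splenic TRM against TEM, Isg15 rose by 1.73 ± 0.24. Among the interferon-stimulated genes, 8 of 24 rose, 2 fell and 14 did not pass (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00783 up, adjusted p = 0.207 with an estimated correlation). Slc2a3, a glucose transporter, rose by 1.92 ± 0.17 and Il1rl1, the IL-33 receptor, by 1.36 ± 0.30. Among the glycolysis genes, 2 of 19 rose and 17 did not pass (1 higher adjusted over the list alone, camera adjusted p = 0.00307 up, adjusted p = 0.157 with an estimated correlation).

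Of the tests that follow, the 2 positions of the library labelled TCM replicate 3 were written down before they were computed, though after its correlations and principal components had been seen, and the others were chosen after the result was seen. TEM libraries counted genes that TCM and splenic TRM libraries did not. Of 24515 genes with no count in those groups, 13047 (53.2%) had counts in TEM, against 23.4% in FRT, 7.94% in IEL and 12.4% in LP TRM. Greater depth is argued against, as the deepest library counted 1.83% of olfactory receptor genes and 10 libraries were deeper than each TEM library. FRT replicates 1 and 2 argue against stromal RNA (at most 1.65% at stroma sums of 3364 to 3436 CPM, TEM 38.6 to 48.6). Replicate 3 (13.4% at 4384) does not. A background in proportion to gene length, such as genomic DNA, stays open. Across these genes, which are not independent replicates, TEM counts had a Spearman rho of 0.593 with exonic length.

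The library labelled TCM replicate 3 stood apart from TCM replicates 5 and 6, at a coefficient of variation of 12.2 and 11.6% for abundant genes. A wrong label stays open. Over 1574 genes that part TCM replicates 5 and 6 from TEM, the library lay at a median of 0.373 of the way to TEM (quartiles 0.212 and 0.524). Over 860 genes that part them from splenic TRM it lay at 0.374 (quartiles 0.158 and 0.610), so that neither label can be excluded nor shown. No biological explanation was tested. The labels number this sample 12 and TCM replicates 5 and 6 as 7 and 8, and they number FRT replicate 3 as 93 and the others 23 to 35.

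Other splits of the compared libraries, fitted on them alone, were counted, with each library taken as a separate sample, which the sources used here do not state. On that footing chance can be excluded for mucosal TRM against circulating cells, where 1 of 100 splits, the real one, called as many as 4777 genes and the highest other called 1839. It can be excluded for mucosal TRM against TCM, with 1 of 100 (2925 and 2263), though with close libraries taken as 1 sample each the splits would be too few for a share under 0.05. For mucosal against splenic TRM, the real split called 2045 genes and another 3136. That other split set FRT libraries against all other TRM and points to a structure of the samples, so that the count excludes nothing there either. With 10 splits, a share under 0.05 cannot be had. There the real split called 5997 genes for FRT TRM against TEM, 7619 for LP TRM against TEM, 4651 for splenic TRM against TEM, 2463 for splenic TRM against TCM, 4157 for TEM against TCM and 3645 for FRT against LP TRM, and the highest other called 0 in each by edgeR.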
